A study of Acinetobacter baylyi ADP1 with 21 samples.

How the data were processed

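Messenger RNA was profiled by Illumina HiSeq sequencing in Acinetobacter baylyi ADP1, a naturally transformable soil bacterium, after 2 h in phosphate-buffered saline with a small carbon supply. There were 7 groups of 3 libraries: an unexposed control, silver nanoparticles or silver ion at 1 mg/L, copper oxide nanoparticles or copper ion at 1 mg/L, and zinc oxide nanoparticles or zinc ion at 10 mg/L. The group of each of the 21 libraries was taken from the sample labels. The control columns of the table carry an abbreviated name and were matched to the control samples because the table names them as its reference. Columns whose names join a metal to the letter P were read as its ion, with P for plus. The zinc nanoparticle columns do not name the oxide and were read as zinc oxide, the only zinc nanoparticle here. Comparisons of nanoparticle with ion rest on this reading. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

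The deposited table gives FPKM (fragments scaled by gene length and by mapped fragments) per library for 3359 genes, per the file headers. Cufflinks 2.2.1 made these values, per the submitters' processing notes, and whether a further scaling was applied between libraries is not given in the sources used here. The aligner and its version are not given in the sources used here. Gene coordinates, locus tags and product names were used as the deposited table gives them, with positions counted from 1. A symbol came from the gene column or, where that holds only a locus tag, from a protein name in the product text. The products of tolC, cusA, gntR, gntP, oprD, tetR, tonB, iucA, rcnB, phzF, chbG, bspA, comEA and the first pilT gene name only a family. These labels mark family members, not identified genes. Symbols were found for 713 of the genes tested, and locus tags were used for the rest. The table assigns 649 of the tested genes to a locus span shared with a neighbour, which is common for bacterial genes in operons; values of such neighbours may share fragments and are less certain, and no coordinates are printed for them. All spans of genes with a locus of their own and a product name were divisible by 3, so the lengths of these genes are coding lengths. Genes without a product name were not checked in this way. Whether fragments were assigned by strand is not given in the sources used here.

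FPKM values are not counts, so no count model was used. Low values lay on steps of whole fragments, and the value of 1 fragment was recovered from the spacing of these steps in 1644 genes of at least 700 bases. In every library, 100% of low values (up to 15 fragments) lay within 0.05 of a whole fragment. Summed over those genes, 19 libraries held between 464691 and 1286868 fragments, copper ion replicate 1 held 5216, and zinc ion replicate 2 held 5991. The median gene among those used for depth had 82.1 to 226 fragments in the 19 deep libraries and at most 2 in the shallow pair. These sums cover only the genes used and describe relative depth, not total sequencing. For 11 highly expressed genes, whose status column reads HIDATA, all 18 exposed libraries were listed at 0 while the controls held at least 2353 FPKM; these genes, which include nuoI, nuoK, cytochrome o ubiquinol oxidase subunit I and ssrS, were left out of every test. Genes with FPKM of at least 1 in at least 3 libraries were tested, which left 3244.

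FPKM was analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. A linear model with 1 mean per group was fitted jointly to all 21 libraries with limma 3.58.1 in R 4.3.3, with a trend of the variance on mean expression, and 9 comparisons were drawn from it: 6 against control and 3 of nanoparticle against ion. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, two-sided, with no minimum fold. The filter, pseudocount, design and threshold were set before the data were examined. On simulated data built from the AgNP comparison, this fit recovered 1% of genes changed by 1 on the log2 scale and 26% of genes changed by 2, with 1 false call. The same fit without the shallow libraries recovered 45% and 89%, with 6 false calls. Every simulated library had the spread pooled over groups, which the shallow libraries widen when included. The 1% and 26% are therefore not the power of the real AgNP comparison. Leaving out the shallow libraries was an alternative added after their depth was seen, and its values are given beside the main ones as "deep libraries only". All comparisons came from the joint fit, so the shallow libraries widen the pooled spread of every comparison, including those without copper ion or zinc ion.

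The 19 gene lists fixed before the data were examined covered competence and DNA uptake, oxidative stress and thiol redox, SOS response and DNA repair, copper and silver efflux and resistance, zinc and other divalent metal transport, chaperones and proteases, iron uptake and storage, iron-sulfur cluster assembly, outer membrane and envelope, multidrug efflux, ribosomal proteins, respiratory chain and ATP synthase, TCA and glyoxylate cycle, sulfur assimilation and sulfonate use, aromatic compound catabolism, type VI secretion, fatty acid and poly-storage lipid metabolism, rRNA and tRNA genes, and mobile elements and phage. Lists were matched on symbol or product name. By symbol, the copper and silver list holds actP, whose product here is an acetate symporter. In the same way the TCA list holds acnD, whose product here is a 2-methylisocitrate dehydratase. Because few symbols are given, several matched few genes, and 6 lists by product name were added after the product names were seen: respiratory enzymes and ATP synthase, TCA and glyoxylate cycle enzymes, aromatic catabolism, pili and competence, efflux pump subunits, and membrane transporters. The last was written after genes lower in all 6 exposures had been seen. Lists were tested with camera from limma at an inter-gene correlation of 0.01, adjusted over all lists and comparisons, with the fixed and the added lists adjusted apart. Camera with an estimated correlation and fry were run beside it. On simulated data, a shift of the ribosomal protein list by 0.7 was called by camera, and 0 other lists passed. The simulated genes varied independently, so this could not show false calls that arise from correlation between genes.

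Named genes followed a rule written before the data were examined. For each comparison against control it takes the 8 largest changes in each direction among called genes with an informative product whose exposed libraries all lie on 1 side of the controls. It adds up to 4 called members of each fixed list past its test, and a fixed set that includes pilT, recA, comEA, cusA and dnaK. For nanoparticle against ion it takes 4 in each direction. Genes named outside the rule are said to be chosen after their values were seen. Agreement between nanoparticle and ion was measured across genes by the correlation and covariance of their fold changes, and by the overlap that independent lists would give. Beside these stand 100 simulations of unchanged groups with shared controls. Each simulation redrew all libraries, the controls included, with the spread pooled over groups. The alternatives tried were median-of-ratios scaling, quantile normalization, other pseudocounts and filters, a fit of only the groups compared, a replicate block, and leaving out each library. Computations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.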

Results

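The series measured how the transcripts of Acinetobacter baylyi ADP1 respond within 2 h to 3 metals, each given as a nanoparticle or as dissolved ion, and it has 3 libraries for each of 6 exposures and 1 control. Of the 21 libraries, 19 had a similar depth, between 464691 and 1286868 fragments over the genes used to measure it. Copper ion replicate 1, with 5216, and zinc ion replicate 2, with 5991, were shallow: 1014 and 1248 genes were listed at 0 in them, against 6 to 37 in the other libraries. Because all groups share 1 estimate of the spread, these libraries entered every comparison; leaving both out raised the number of genes called in all 9. Counts from the 19 deep libraries are given beside the main ones. Of the genes called in each comparison with all libraries, all were also called in the same direction in the deep libraries, except for 1 of 207 for zinc ion. Median log2 fold changes over all genes were 0.12 for AgNP, 0.18 for Ag ion, -0.32 for Cu ion and -0.53 for Zn ion against control. Median-of-ratios scaling moved them to -0.01, 0.07, -0.45 and -0.64, quantile normalization moved those of Cu ion and Zn ion to 0.04 and 0.05, and the deep libraries alone gave -0.16 and 0.09 for these ions. Nanoparticle minus ion medians were 0.23 for copper and 0.48 for zinc, and -0.09 and -0.05 after quantile normalization. Changes below are relative to the values as deposited.

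**Figure D1:**
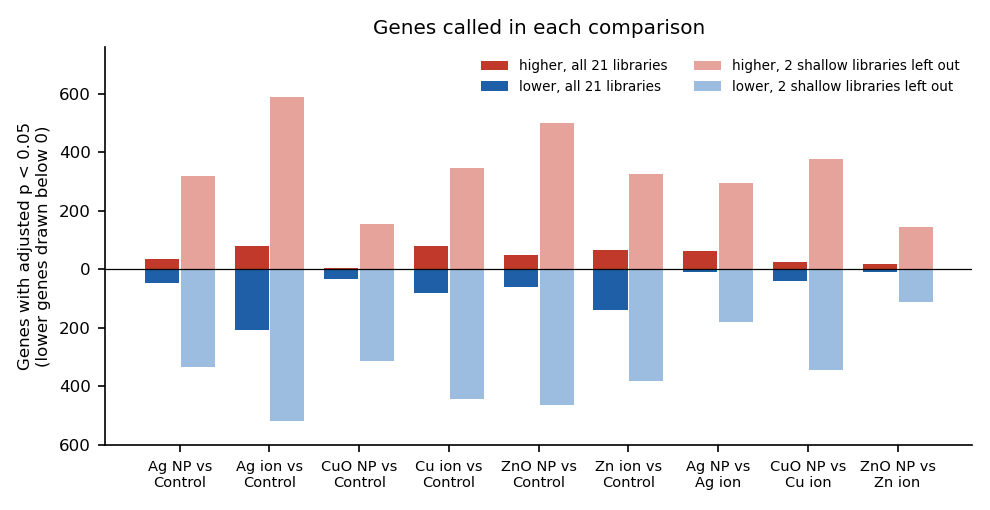
Number of genes with an adjusted p under 0.05 in each of 9 comparisons, higher genes above 0 and lower genes below it. Dark bars are the fit of all 21 libraries and pale bars the fit of the 19 deep libraries; for silver ion against control the bars stand at 81 and 207, and at 588 and 518.

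The AgNP comparison asks what silver nanoparticles changed. Named below are single genes past the test, and they do not stand for their functional groups. The DNA helicase ACIAD_RS10005 had 244 ± 31.1 FPKM (SD, n = 3) against 8.91 ± 9.16 in controls, 32.2-fold higher, the helicase ACIAD_RS09960 was 25.3-fold higher, and bspA, annotated as a leucine-rich repeat surface protein, was 16.5-fold higher. These 3 genes lie among a run of neighbours described further below. Of the chaperones, groES (2776997 to 2777287), a partner of the GroEL folding machine, rose 3.11-fold to 3723 ± 930 FPKM. The chaperone htpG (316092 to 318014) rose 2.83-fold and clpB (1262777 to 1265356), which dissolves protein aggregates, rose 2.73-fold. The chaperone and protease list as a group did not pass (3 of 27 rising, median 0.33, camera adjusted p = 0.0843; adjusted p = 0.962 with an estimated correlation). The methionine sulfoxide reductase msrA (500029 to 500550), which repairs oxidised methionine, had 700 ± 290 FPKM against 219 ± 21.3, and the ribose-phosphate pyrophosphokinase ACIAD_RS04445 (950541 to 951422) rose 3.67-fold.

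Among the genes that fell with AgNP, the OprD family porin oprD (969761 to 971044) had 6.68 ± 0.68 FPKM against 174 ± 87.2, a log2 change of -4.39. The GntR family regulator gntR (2698248 to 2698928) had 502 ± 60.8 against 5648 ± 1530. The MFS transporter ACIAD_RS06625 (1431562 to 1432962) had a log2 change of -3.04, the amino acid permease ACIAD_RS00550 (118628 to 120052) one of -2.89, to 1240 ± 102 FPKM, and the MFS transporter ACIAD_RS08180 one of -2.64. The oxidoreductase ACIAD_RS16420 changed by -2.55, the triacylglycerol lipase ACIAD_RS14975 by -2.52 and the acetate symporter actP (3387996 to 3389711) by -2.21. The largest limma Benjamini-Hochberg adjusted p among the genes named as changed was 0.0443. The respiratory chain list of 5 genes was lower (median -0.99, camera adjusted p = 0.0222), with adjusted p = 0.868 with an estimated correlation; 0 of its members fell singly, over all genes or adjusted over the list alone. Of the fixed genes, recA was at 0.39 (adjusted p = 1 by limma with Benjamini-Hochberg adjustment), dnaK at 0.92 (0.553), cusA at -1.25 (0.143), comEA at 0.24 and the pilT genes at 0.64 and 0.59, none past the test with all libraries. In the deep libraries, with the same fold changes, dnaK and cusA passed (limma, Benjamini-Hochberg adjusted p = 0.00576 and 0.0067) and the others did not. In all, 35 genes were higher and 45 lower, against 318 and 333 in the deep libraries. The total of 80 was 45 without control replicate 1, 39 without control 2, 49 and 47 without AgNP replicates 1 and 2, 255 without copper ion replicate 1 and 166 without zinc ion replicate 2, and higher calls made up 43.8% of it and 33.3% after median-of-ratios scaling.

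Silver ion changed more genes in the same fit. Genes of a phage-like region were again among those that rose, with the phage antirepressor ACIAD_RS09940 (2149543 to 2150094) 22.8-fold higher, the helicases ACIAD_RS10005 and ACIAD_RS09960 16.4-fold and 12.4-fold higher, and bspA 7.69-fold higher. The META domain protein ACIAD_RS08175 (1778317 to 1778754) rose 15.3-fold to 875 ± 253 FPKM (SD, n = 3), and the alkene reductase ACIAD_RS15805 (3420162 to 3421232), a flavin enzyme, rose 6.44-fold to 787 ± 98.1. A helix-turn-helix regulator, ACIAD_RS12580, was 9.68-fold higher and the DNA-binding protein ACIAD_RS09795 was 7.34-fold higher. Among the genes that fell, the MFS transporter ACIAD_RS04520 (968383 to 969729) changed by -5.10 on the log2 scale. Both subunits of the NAD(P) transhydrogenase, which passes electrons between the nicotinamide cofactors, fell, with log2 changes of -4.73 for ACIAD_RS13920 and -4.40 for ACIAD_RS13930. ACIAD_RS08180 changed by -4.19, oprD by -3.68, the amino acid permease ACIAD_RS15600 by -3.68 and the branched-chain amino acid carrier ACIAD_RS09155 by -3.50. The efflux adaptor ACIAD_RS15280 changed by -3.31 and the neighbouring CusA/CzcA family pump cusA by -3.20, to 20.5 ± 2.53 FPKM against 211 ± 100.

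The respiratory chain list was lower with silver ion (median -1.26, camera adjusted p = 0.0208; adjusted p = 0.868 with an estimated correlation). Of its 5 genes, 2 fell, nuoN (-2.32) and nuoH (-1.92), and 4 fell adjusted over the list alone. Between nuoH and nuoN lie nuoI and nuoK, left out because they are listed at 0 in all exposed libraries. The type VI secretion list of 15 genes, a contractile weapon against other cells, was lower (median -0.51, camera adjusted p = 0.0208; adjusted p = 0.225 with an estimated correlation), with 2 falling, tssM (-3.10) and the sheath subunit ACIAD_RS12235 (-0.95), and 3 adjusted over the list alone. Of the fixed genes not past the test with all libraries, dnaK was at 1.55 (limma, Benjamini-Hochberg adjusted p = 0.0559), recA at 0.78 (0.248), comEA at 0.36, and the pilT genes at 0.84 and 0.94. With the deep libraries and the same fold changes, dnaK (limma, Benjamini-Hochberg adjusted p = 2.48e-05), recA (0.000667) and both pilT genes (0.00732 and 0.0283) passed, and comEA did not. In all, 81 genes were higher and 207 lower, the largest limma Benjamini-Hochberg adjusted p of a named call being 0.0498. In the deep libraries 588 were higher and 518 lower, and the total of 288 was 517 without copper ion replicate 1 and 436 without zinc ion replicate 2. Higher calls made up 28.1% of it and 38.3% after quantile normalization.

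Set directly against silver ion, AgNP had 62 genes higher and 9 lower, and 296 and 178 in the deep libraries. The ribose-phosphate pyrophosphokinase ACIAD_RS04445 was 7.08-fold higher with nanoparticles, ACIAD_RS15600 was 6.73-fold higher, the thin pilus adhesin acuG (384773 to 385822) was 5.74-fold higher at 687 ± 98.5 FPKM (SD, n = 3). The quinone-linked malate dehydrogenase ACIAD_RS04640 was 5.42-fold higher. Lower with nanoparticles were the alkene reductase ACIAD_RS15805 (-2.62), the flavin oxidoreductase ACIAD_RS11060 (-2.58), the ATP-grasp protein ACIAD_RS11150 (-1.32) and the polyisoprenoid-binding protein ACIAD_RS09360 (-1.31), with limma Benjamini-Hochberg adjusted p up to 0.024. The multidrug efflux list of 33 genes was higher with nanoparticles (median 0.36, camera adjusted p = 0.0208; adjusted p = 0.499 with an estimated correlation), 2 of them rising, and 2 adjusted over the list alone. The copper and silver list of 6 was also higher (median 0.98, camera adjusted p = 0.0402; adjusted p = 0.499 with an estimated correlation), with 1 rising, and 1 adjusted over the list alone. The total of 71 was 47 and 32 without AgNP replicates 1 and 2, 37 and 42 without Ag ion replicates 2 and 3, 195 without copper ion replicate 1 and 135 without zinc ion replicate 2. Higher calls made up 87.3% of it and 70.1% after quantile normalization.

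A run of 41 neighbouring genes (2128812 to 2162508, 33.7 kb), picked after its fold changes were seen, holds the phage antirepressor and both helicases named above; 28 of its products are hypothetical. Its median log2 change was 4.66 with AgNP, 25.3-fold, and 3.64 with Ag ion, 12.4-fold, and 24 of the 41 genes rose in each, 39 and 38 in the deep libraries. Medians were 0.45 with CuO, 0.34 with copper ion (-0.23 in the deep libraries), 0.12 with ZnO and -0.04 with zinc ion, where limma called 0 genes in all libraries (2, 7, 1 and 1 at an unadjusted p under 0.05). In the deep libraries 3, 1, 5 and 2 rose and 1, 2, 1 and 0 fell. The median FPKM of the run was 84.7 to 229 in the 6 silver libraries, at most 7.56 in the controls and at most 8.88 in the other deep exposed libraries. Between AgNP and Ag ion the median difference was 0.96, with 0 genes called by limma in all libraries (1 at an unadjusted p under 0.05) and 3 in the deep ones. The selection on these same values makes the run a description, not an independent test.

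**Figure D2:**
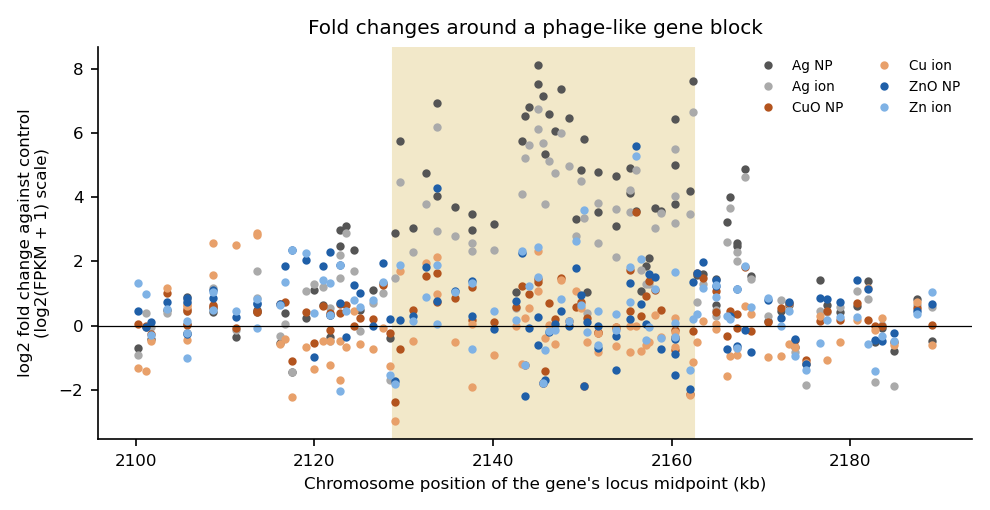
Log2 fold change against control on the log2(FPKM + 1) scale in the deep libraries, by position in kb, for genes around the run of 41 neighbours, which is shaded. Each point is a gene in 1 exposure; the shaded genes have medians of 4.66 with AgNP and 3.64 with Ag ion, and some genes outside the shading are also higher with silver.

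Copper oxide nanoparticles had the fewest genes called against control in the joint fits, with all and with the deep libraries, but not in fits of only the groups compared (92, against 9 for copper ion and 27 for zinc ion). A siderophore receptor, ACIAD_RS02415 (517500 to 519695), rose 4.25-fold to 173 ± 23.5 FPKM (SD, n = 3), the cadmium-type P-type ATPase ACIAD_RS10970, an exporter of metal ions, rose 3.34-fold to 669 ± 89.9. ACIAD_RS04445 rose 3.84-fold and antC (2625014 to 2626045), the electron transfer part of anthranilate dioxygenase, rose 2.55-fold. Several transporters were lower, with log2 changes of -2.71 for ACIAD_RS06625, -2.66 for ACIAD_RS00550, -1.94 for the permease gntP (2465288 to 2466706), -1.83 for the TRAP transporter ACIAD_RS14430, -1.77 for the L-lactate permease ACIAD_RS00495 and -1.84 for the efflux adaptor ACIAD_RS16390. The lipase ACIAD_RS14975 changed by -2.22 and the polysaccharide synthase ACIAD_RS04750 (1022597 to 1023865), of the biofilm polymer poly-N-acetylglucosamine, by -2.15; the largest limma Benjamini-Hochberg adjusted p among these genes was 0.0314. The multicopper oxidase ACIAD_RS03165, chosen after its values were seen, was between 372 and 620 FPKM in the 3 CuO libraries and 41.9 ± 5.23 in controls. Its log2 change of 3.54 had a limma Benjamini-Hochberg adjusted p of 0.0969 with all libraries (SE 0.943), among them a 0 in zinc ion replicate 2, and 5.72e-09 in the deep libraries (SE 0.192). Of the fixed genes, cusA was at -1.14 (limma, Benjamini-Hochberg adjusted p = 0.264), recA at 0.20, dnaK at 0.40, comEA at -0.13 and the pilT genes at 0.36 and 0.52, none past the test with all libraries; in the deep libraries cusA alone passed (0.0159, the fold change being the same). None of the 19 fixed lists passed by camera, the closest being iron uptake (adjusted p = 0.0564, median 0.52) and chaperones (adjusted p = 0.0996). In all, 5 genes were higher and 32 lower, and 156 and 312 in the deep libraries. The total of 37 was 15, 8 and 14 without CuO replicates 1, 2 and 3, 11 and 9 without control replicates 1 and 2, 143 without copper ion replicate 1 and 95 without zinc ion replicate 2.

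With copper ion, the oxidative stress list (4 of 46 rising, median -0.04, camera adjusted p = 0.0996; adjusted p = 0.962 with an estimated correlation) and the copper and silver list (2 of 6 rising and 1 falling, median 1.28, camera adjusted p = 0.141; adjusted p = 0.868 with an estimated correlation) did not pass as groups. The falling member of the copper and silver list was actP, the acetate symporter matched by symbol. The alkyl hydroperoxide reductase, which reduces peroxides, rose in both its parts. Subunit C ACIAD_RS02010 (432824 to 433387) rose 42.9-fold, to 2160 ± 754 FPKM (SD, n = 3) against 49.9 ± 21.6. The F subunits ACIAD_RS05680 (1234047 to 1235606) and ACIAD_RS10305 (2221393 to 2222952) rose 36.8-fold and 25.5-fold. Both have the same product name and spans of equal length, and whether they share fragments was not tested. The TolC family gene tolC ACIAD_RS15285 rose 16.5-fold and copper resistance protein B ACIAD_RS03170 rose 13.0-fold (3.70 on the log2 scale, 3.09 in the deep libraries). The multicopper oxidase ACIAD_RS03165 rose 12.4-fold and antC rose 10.6-fold, and rcnB (45901 to 46203), of a family of periplasmic metal proteins, rose 9.86-fold to 2104 ± 135. The iron uptake list of 30 genes was higher (median 0.79, camera adjusted p = 0.0208; adjusted p = 0.225 with an estimated correlation), with 4 rising, and 7 adjusted over the list alone: iucA ACIAD_RS09730 rose 7.63-fold, the siderophore synthesis gene ACIAD_RS09745 rose 6.66-fold, ACIAD_RS02415 rose 4.48-fold and tonB ACIAD_RS02300, which powers outer membrane receptors, rose 3.47-fold. The TCA list of 3 was higher (median 0.84, camera adjusted p = 0.0402, and 0.567 as adjusted p with an estimated correlation). Its 1 call was acnD, rising 4.64-fold, with 2 adjusted over the list alone. This gene was matched by symbol and its product here is a 2-methylisocitrate dehydratase, so the call does not stand for TCA enzymes.

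Falls with copper ion rest partly on values of 0 in the shallow replicate, so the deep value is given second. The gene phzF (1191486 to 1192316) changed by -6.23 (deep -4.27), ACIAD_RS13920 by -4.83 (-2.48), the ring-hydroxylating dioxygenase ACIAD_RS04515 (966498 to 967574) by -4.23 (-3.13), the chloride channel ACIAD_RS05485 by -4.17 (-1.93), the ferredoxin reductase ACIAD_RS00245 by -4.06 (-1.91), the PAAR protein ACIAD_RS00265 by -3.73 (-2.19) and the transporter ACIAD_RS01990 by -3.19 (-1.92). The HPP family gene ACIAD_RS16860 was listed at 0 in all 3 libraries and had 152 ± 148 FPKM in controls. The largest limma Benjamini-Hochberg adjusted p among these genes was 0.0491. Of the fixed genes, cusA was at 0.85 (limma, Benjamini-Hochberg adjusted p = 0.236), dnaK at 0.88 (0.287), recA at 0.07, comEA at 0.64 and the pilT genes at -1.83 and 0.60, none past the test with all libraries. Deep libraries alone gave dnaK (1.73, limma, Benjamini-Hochberg adjusted p = 0.000106), cusA (1.31, 0.00868) and recA (0.66, 0.00858) past the test, but not comEA (-0.99) or the pilT genes (0.32 and 0.26). In all, 79 genes were higher and 82 lower, and 346 and 442 in the deep libraries. The total of 161 was 304, 254 and 284 without copper ion replicates 1, 2 and 3, 82, 91 and 84 without control replicates 1, 2 and 3, and 372 without zinc ion replicate 2. Higher calls were 49.1% of the 161, 54.9% and 53.8% without control replicates 1 and 2, and 56.9%, 26.8% and 28.2% without copper ion replicates 1, 2 and 3. In a fit of only the groups compared 9 genes were called.

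Between the copper forms, CuO nanoparticles had 25 genes higher and 40 lower than copper ion, and 377 and 344 in the deep libraries. The balance turned to 120 higher and 40 lower without copper ion replicate 2, and to 116 and 36 without copper ion replicate 3. A fit of only the 2 groups called 0 genes by limma (284 at an unadjusted p under 0.05). The peroxide genes were lower with nanoparticles, ACIAD_RS05680 (-3.85), ACIAD_RS10305 (-3.84) and ACIAD_RS02010 (-3.15), as was tolC (-4.32), at 33.0 ± 9.57 FPKM (SD, n = 3) against 696 ± 251. Higher with nanoparticles were aceI (1967881 to 1968306), a chlorhexidine exporter, by 6.18 on the log2 scale (3.28 in the deep libraries), the esterase ACIAD_RS04920 by 4.55 (2.54) and ACIAD_RS00265, 16.0-fold (2.46 on the log2 scale in the deep libraries); ACIAD_RS16860 was listed at 0 with copper ion and had 180 ± 140 FPKM with nanoparticles. The largest limma Benjamini-Hochberg adjusted p of these was 0.0379. The total of 65 was 16, 24 and 19 without CuO replicates 1, 2 and 3, 202, 160 and 152 without copper ion replicates 1, 2 and 3, and 270 without zinc ion replicate 2.

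With ZnO nanoparticles, 3 neighbouring efflux genes were among the largest rises. The TolC family gene tolC rose 38.5-fold to 1566 ± 364 FPKM (SD, n = 3) against 43.3 ± 21.5. Its neighbour adaptor ACIAD_RS15280 rose 9.36-fold and the CusA/CzcA family pump cusA rose 7.94-fold to 1611 ± 472. These 3 genes share a locus span. The META domain protein ACIAD_RS08175 rose 17.2-fold, the deacetylase chbG rose 15.1-fold and alkyl hydroperoxide reductase C ACIAD_RS02010 rose 12.4-fold. The lipid A phosphoethanolamine transferase ACIAD_RS06575 (1417886 to 1419538), which alters the outer membrane surface, rose 6.13-fold and the hydrolase ACIAD_RS12450 rose 5.65-fold. Lower were oprD (-4.58), the dioxygenase ACIAD_RS04515 (-3.31), ACIAD_RS06625 (-2.99), ACIAD_RS00550 (-2.73), ACIAD_RS14975 (-2.42), ACIAD_RS14430 (-2.06), gntP (-2.02) and the secretion gene ACIAD_RS01370 (-1.99), the largest limma Benjamini-Hochberg adjusted p being 0.049. Of the fixed genes not past the test, recA was at 0.25, dnaK at 0.59 (limma, Benjamini-Hochberg adjusted p = 0.827), comEA at 0.40 and the pilT genes at 0.64 and -0.53. With the deep libraries and the same fold changes, dnaK and the first pilT gene passed (limma, Benjamini-Hochberg adjusted p = 0.0457 and 0.0377) and the others did not. None of the 19 fixed lists passed by camera, the closest being oxidative stress (adjusted p = 0.0642, median 0.56), in which 2 genes rose and, adjusted over the list alone, 5 rose and 1 fell. In all, 49 genes were higher and 59 lower, and 499 and 463 in the deep libraries. The total of 108 was 41, 50 and 64 without ZnO replicates 1, 2 and 3, 51 (28 higher and 23 lower) and 55 without control replicates 1 and 2, 351 without copper ion replicate 1 and 218 without zinc ion replicate 2.

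With zinc ion, the genes named are single calls. The alkyl hydroperoxide reductase F subunits ACIAD_RS05680 and ACIAD_RS10305 rose 34.6-fold and 21.1-fold, the former to 807 ± 78.3 FPKM (SD, n = 3), and subunit C ACIAD_RS02010 rose 12.8-fold. The small heat shock gene ACIAD_RS13800 (2980060 to 2980527) rose 15.8-fold, its neighbour the thiol:disulfide oxidoreductase ACIAD_RS13795 (2979141 to 2979761) rose 8.32-fold. The sulfate-binding transport protein ACIAD_RS11785 (2549449 to 2550450) rose 11.1-fold, tolC rose 8.62-fold and the alkene reductase ACIAD_RS15805 rose 8.54-fold. Falls, with the deep value second, were phzF by -6.02 (-3.96), oprD by -5.44 (-4.49), ACIAD_RS13930 by -4.91 (-2.90), the undecaprenyl-diphosphate phosphatases ACIAD_RS03130 and ACIAD_RS07535, which recycle the cell wall lipid carrier, by -4.44 (-2.07) and -4.40 (-2.03), the symporter ACIAD_RS01515 by -4.37 (-2.58), the pyrimidine permease ACIAD_RS16405 by -4.28 (-2.13) and ACIAD_RS04515 by -4.26 (-3.17). The largest limma Benjamini-Hochberg adjusted p among these genes was 0.0356. Of the fixed genes, dnaK was at 1.57 (limma, Benjamini-Hochberg adjusted p = 0.0643), cusA at -0.35, recA at 0.03, comEA at -1.14 and the pilT genes at 0.46 and 0.74, none past the test with all libraries. Of these, dnaK passed with the deep libraries (1.69, limma, Benjamini-Hochberg adjusted p = 0.000107), while cusA (-0.15), recA (0.14), comEA (1.11) and the pilT genes (0.28 and 0.60) did not. None of the 19 fixed lists passed by camera, the closest being ribosomal proteins (adjusted p = 0.0703, median -0.97). In all, 68 genes were higher and 139 lower, and 325 and 380 in the deep libraries. The total of 207 was 402 without zinc ion replicate 3, 108 and 134 without control replicates 1 and 2, and 581 without copper ion replicate 1, and a fit of only the groups compared called 27.

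Between the zinc forms, the nanoparticles had 20 genes higher and 9 lower, and 144 and 111 in the deep libraries. Fitting only the 2 groups gave 0 calls by limma (342 at an unadjusted p under 0.05). The efflux genes were higher with nanoparticles, cusA 10.1-fold, ACIAD_RS15280 6.29-fold and tolC 4.47-fold, as was the symporter ACIAD_RS06160 (1335452 to 1336750), 6.51-fold (2.70 on the log2 scale, 1.90 in the deep libraries). Lower with nanoparticles were the peroxide genes ACIAD_RS05680 (-3.55) and ACIAD_RS10305 (-2.72), the amino acid synthesis family gene ACIAD_RS11565 (-4.25) and the TetR/AcrR family regulator tetR ACIAD_RS12420 (-2.53), with limma Benjamini-Hochberg adjusted p up to 0.0317. The total of 29 was 7 without any 1 of the ZnO replicates, 15 and 47 without zinc ion replicates 1 and 3, and 187 without copper ion replicate 1. Higher calls made up 69.0% of it and 49.3% after quantile normalization.

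**Figure D3:**
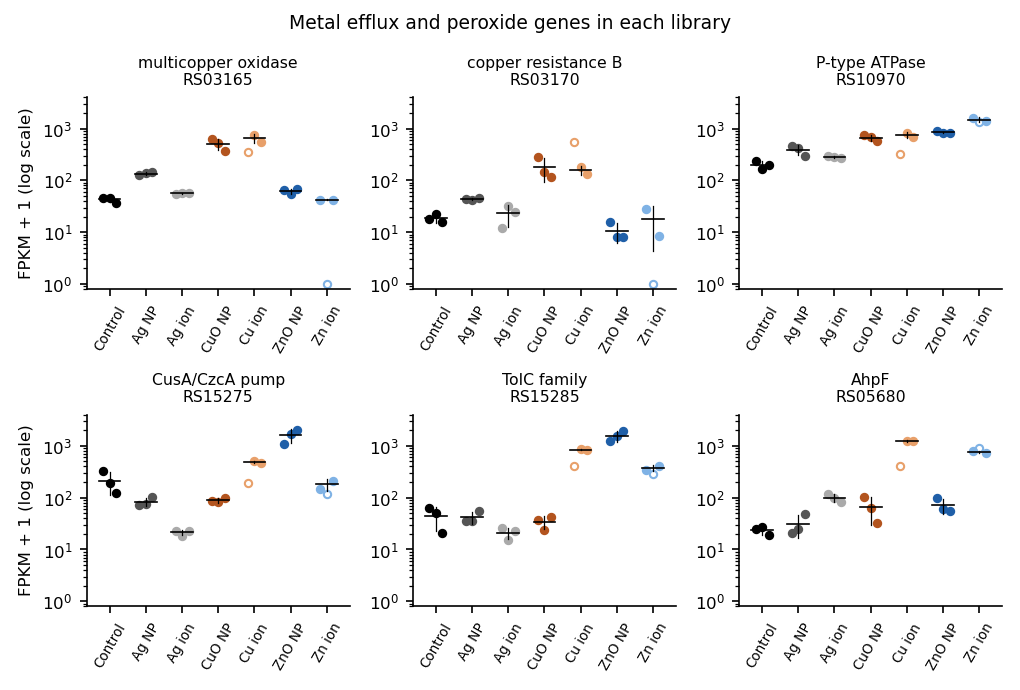
FPKM + 1 on a log axis of 6 metal and peroxide genes in each library, by group. Open circles are the shallow libraries, and horizontal and vertical lines are the mean and SD of the other libraries; in the deep libraries copper ion changed the F subunit ACIAD_RS05680 by 5.73 on the log2 scale and ZnO nanoparticles changed cusA by 2.99.

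How far nanoparticle and ion of 1 metal moved the same genes was measured across genes, which are not independent replicates. The correlation of fold changes was 0.771 for silver, 0.234 for copper and 0.472 for zinc, and simulated unchanged groups with shared controls gave 0.499, 0.497 and 0.500. The covariances were 0.813, 0.268 and 0.659, and differed from the simulated ones by 0.238, -0.303 and 0.083. The shallow libraries widen the spread given to every simulated library: the simulated copper covariance was 0.571 with them and 0.102 without. The all-library simulations therefore cannot show a lack of agreement for copper or zinc. In the deep libraries the correlations were 0.771, 0.394 and 0.703, the simulated ones 0.503, 0.449 and 0.452, and the differences of covariance 0.711, 0.178 and 0.554. Called in the same direction were 70 genes for silver (31 higher, 39 lower, where independent lists would share 0.874 and 2.87), 29 for copper (4 and 25, against 0.122 and 0.809) and 62 for zinc (19 and 43, against 1.03 and 2.53), and 480, 230 and 427 in the deep libraries; 0 were called in opposite directions, and in the deep libraries 2, 12 and 4. The simulations of all libraries shared 0 calls, and those of the deep libraries at most 1 for silver and 0 for copper and zinc. Simulated unchanged groups give few calls in either comparison, so few shared calls were likely beforehand. The 3 controls cannot be split into groups of at least 2 libraries, so part of the excess may come from the shared controls.

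A response common to the 3 metals in both forms was asked for by counting genes called in the same direction in all 6 exposures. There were 0 higher and 14 lower, where independent lists would share 1.04e-08 and 5.58e-07, and 100 simulations gave 0. The 6 comparisons share their controls, so their lists are not independent. Simulated unchanged groups give few calls in any 1 comparison, so a count of 0 in all 6 was likely beforehand. Neither value therefore excludes chance or a shift of the shared controls. The genes, named in full after the count was seen, were the amino acid permeases ACIAD_RS00550 and ACIAD_RS05870, the MFS transporters ACIAD_RS06625, ACIAD_RS09075 and ACIAD_RS14360, the branched-chain amino acid carrier ACIAD_RS09155, the TRAP transporter ACIAD_RS14430, actP, the carbon starvation gene ACIAD_RS10105, the polysaccharide synthase ACIAD_RS04750, the lipase ACIAD_RS14975, the hydrolase ACIAD_RS11990, ACIAD_RS10980 and the phosphate sensor phoR. Mean log2 changes over the exposures ran from -2.89 for ACIAD_RS00550 to -1.10 for ACIAD_RS09075. The count was 5 without control replicate 1 and 5 without control replicate 2, and the deep libraries gave 13 higher and 98 lower. After median-of-ratios scaling of all libraries 8 of the 14 were still called lower in all 6 exposures. Where calls ended, the median change did not shrink (-1.14 before and -1.18 after with CuO, -1.0 and -1.04 with ZnO) while the SE grew. With this scaling and the shallow libraries left out, all 14 were called lower. The 13, which include htpG, msrA, clpB, the peroxiredoxin ACIAD_RS09650 and cysD, were looked at after the shallow libraries had been found.

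The fixed lists not yet described passed the test in none of the 9 comparisons of all libraries. The lowest camera adjusted p over the 9 was 0.0996 for competence and DNA uptake (12 genes, of which 1 fell with copper ion and the rest did not pass), 0.0642 for oxidative stress, 0.0781 for SOS and DNA repair, 0.0781 for chaperones, 0.0781 for iron-sulfur assembly, 0.403 for zinc and divalent metal transport, 0.412 for outer membrane, 0.0703 for ribosomal proteins, 0.302 for sulfur assimilation, 0.419 for aromatic catabolism, 0.265 for fatty acid and storage lipid, 0.266 for rRNA and tRNA genes and 0.256 for mobile elements and phage. Of the 171 tests of fixed lists, 7 passed and 0 did with an estimated correlation (lowest adjusted p = 0.225), and in 41 tests, none of them called, the median, mean and test of the list differed in sign. With the deep libraries 38 passed, and again 0 with an estimated correlation (lowest adjusted p = 0.196). There, oxidative stress was higher in all 6 exposures, for example with copper ion (median 0.48, 16 of 46 genes rising and 2 falling; 18 and 2 adjusted over the list alone; camera adjusted p = 0.000197, and 0.262 as adjusted p with an estimated correlation), SOS and DNA repair was higher with AgNP and Ag ion (5 and 7 of 21 genes rising; camera adjusted p = 0.0286 and 0.0239, and 0.262 for both as adjusted p with an estimated correlation), and sulfur assimilation was higher with zinc ion (4 of 14 rising; camera adjusted p = 0.00541; adjusted p = 0.196 with an estimated correlation). The ribosomal protein list was at a median of -0.41 with copper ion in all libraries and 0.49 in the deep ones.

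The 6 lists added after the product names were seen gave 26 calls in 54 tests by camera, of which 5 held with an estimated correlation, all of them membrane transporters. That list of 140 genes was lower in all 6 exposures, with 57 genes falling with silver ion (median -1.42, adjusted p = 7.3e-38; adjusted p = 0.0176 with an estimated correlation) and 15 with AgNP. With an estimated correlation it did not pass with copper ion (20 falling, median -0.60, adjusted p = 0.575) or zinc ion (42 falling, median -1.43, adjusted p = 0.0644), and in the deep libraries not with copper ion (0.141), ZnO (0.0745) or zinc ion (0.0545). The list was drawn up after the genes lower in all 6 exposures were seen, so its direction is not independent evidence. Respiratory enzymes and ATP synthase, 29 genes, were lower with both silver forms, CuO and both zinc forms (9 falling with silver ion, median -1.21, adjusted p = 2.47e-09; adjusted p = 0.475 with an estimated correlation). Efflux pump subunits, 40 genes, were lower with AgNP, Ag ion and CuO (14 falling with silver ion, median -1.22, adjusted p = 2.08e-09; adjusted p = 0.0799 with an estimated correlation). TCA enzymes were higher with copper ion (5 of 23 rising and 1 falling, median 0.60, adjusted p = 6.64e-05; adjusted p = 0.575 with an estimated correlation). Pili and competence genes were lower with copper ion (3 of 25 falling, median -0.59, adjusted p = 0.00924) and ZnO nanoparticles (1 falling, median -0.50, adjusted p = 0.00968), both with adjusted p = 0.406 with an estimated correlation. Aromatic catabolism was lower with AgNP (0 of 32 falling, median -0.41, adjusted p = 0.0141; adjusted p = 0.746 with an estimated correlation) and zinc ion (4 falling and 1 rising, median -1.20, adjusted p = 0.031; adjusted p = 0.781 with an estimated correlation). Respiratory enzymes in CuO against copper ion were called lower at a median of -0.19 and a mean of 0.04 (camera adjusted p = 0.0386; adjusted p = 0.829 with an estimated correlation), the 1 called test of these lists whose signs differ.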

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

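The tests of differences between metals were chosen after the data were seen. Whether the nanoparticle minus ion difference itself differs between metals was tested with an interaction term in the joint limma fit. At a Benjamini-Hochberg adjusted p under 0.05 it differed between silver and copper in 43 genes, and in 475 in the deep libraries. Between silver and zinc it differed in 4 genes (156 in the deep libraries), and between copper and zinc in 14 (314 in the deep libraries). Copper ion replicate 1 and zinc ion replicate 2, the shallow libraries, enter these tests directly, and no explanation is offered for the genes.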

How the results depend on the processing

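Every fit without the shallow libraries was chosen after their depth was seen; the other settings were planned before the data were examined, except that leaving out either shallow library was also tried in comparisons that do not hold it. Counts are given in the order AgNP, Ag ion, CuO, copper ion, ZnO and zinc ion against control, then the silver, copper and zinc forms against each other; the main counts were 80, 288, 37, 161, 108, 207, 71, 65 and 29. The counts stayed within 1.5 times these under no filter, a mean FPKM of at least 10, a minimum log2 change of 1 and both other pseudocounts. With the shallow libraries left out they were 651, 1106, 468, 788, 962, 705, 474, 721 and 255. With median-of-ratios scaling as well they were 660, 1031, 475, 761, 960, 701, 478, 748 and 263, and with the replicate block as well, 636, 1079, 437, 709, 946, 667, 456, 607 and 189. Quantile normalization gave 152, 483, 67, 310, 213, 340, 147, 245 and 75. Fits of only the groups compared gave 150, 880, 92, 9, 769, 27, 261, 0 and 0; the last 2, both counted by limma, had 284 and 342 genes at an unadjusted p under 0.05, and each has a shallow library in 1 group. Median-of-ratios scaling moved 4 counts by more than 1.5 times, to 19 for CuO, 106 for copper ion, 40 between the silver forms and 42 between the copper forms. Leave-one-out gave 39 to 255, 197 to 517, 8 to 143, 82 to 372, 41 to 351, 108 to 581, 32 to 195, 16 to 270 and 7 to 187. The highest counts came without copper ion replicate 1, or without zinc ion replicate 2 for copper ion and between the copper forms. The lowest came, in order, without control replicate 2, Ag ion 3, CuO 2, control 1, ZnO 1, control 1, AgNP 2, CuO 1 and any of the ZnO libraries. Where a group is left with few libraries, these are assumed to vary like the other groups.

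The correlation between nanoparticle and ion fold changes was 0.732 for silver, 0.320 for copper and 0.598 for zinc after quantile normalization, and 0.253 for copper after median-of-ratios scaling. With a pseudocount of 0.1 it was 0.192 for copper and 0.398 for zinc, and with 5 it was 0.284 and 0.533. Without the shallow libraries it was 0.394 and 0.703, with median-of-ratios scaling as well 0.392 and 0.704, and with the block as well 0.410 and 0.707. Without 1 control it ran from 0.770 to 0.795 for silver, 0.270 to 0.276 for copper and 0.426 to 0.535 for zinc. Genes changed in all 6 exposures numbered 111 without the shallow libraries, 110 with median-of-ratios scaling as well and 106 with the block as well, and 5 to 13 without 1 control, with 5 without control replicate 1 or 2. Of the fixed lists, 7 tests passed in the main setting, 0 with an estimated correlation, 3 by fry and 17 after quantile normalization. Without the shallow libraries 38 passed, 0 with an estimated correlation, 88 by fry and 36 with the block. The ribosomal protein median reversed without the shallow libraries, to 0.49 with copper ion (0.45 with the block) and -0.54 between the copper forms (-0.50 with the block).

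Among single named genes and lists, no direction called in the main setting reversed under the alternatives run. Those ribosomal medians were not called in the main setting. Some uncalled genes, such as comEA with zinc ion, also changed sign without the shallow libraries. Counting each value once per alternative, 120 passed the threshold in an alternative but not in the main setting. Another 362 passed in the main setting but not in the alternative. The labels do not say whether replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.006 on average over 63 pairs (-0.472 to 0.363, and up to 0.602 in the deep libraries). Of the 63 pairs 13 were over 0.1, and 8 of 21 libraries correlated best with their own number. A low mean does not exclude pairing of some libraries. With the replicate block the counts were 74, 266, 35, 143, 95, 191, 61, 54 and 21, the correlations 0.771, 0.234 and 0.472, the genes changed in all 6 exposures 14, and the list tests passed 7. The cause of the other moves was not tested. At the depth of the shallow libraries the median gene among those used for depth had at most 2 fragments, so a value of 0 there says little of a gene's absence.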

Other observations

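The tests of this part were chosen after the results were seen, except the length correction and the comparison of copper ion replicate 1 with thinned libraries. In the deep libraries several further lists were past the camera test. Copper ion was higher for iron-sulfur cluster assembly (6 of 8 genes rising, median 1.04, adjusted p = 0.00517; adjusted p = 0.196 with an estimated correlation), for copper and silver resistance (5 of 6 rising and 1 falling, median 1.39, adjusted p = 0.00517; adjusted p = 0.196 with an estimated correlation) and for TCA enzymes by product name (17 of 23 rising and 1 falling, median 1.15, adjusted p = 2.05e-10; adjusted p = 0.0919 with an estimated correlation). The falling member of the copper and silver list was again the acetate symporter actP. Pili and competence genes by product name were lower with copper ion (12 of 25 falling, median -0.67, camera adjusted p = 0.000174), and this held with an estimated correlation (adjusted p = 0.0457). In CuO against copper ion the TCA enzymes were lower (15 of 23 falling, median -1.12, adjusted p = 2.96e-09; adjusted p = 0.0981 with an estimated correlation). Of the 14 genes lower in all 6 exposures, 7 had product names that matched the transporter list, which misses the carrier ACIAD_RS09155. The 7 are 50% against 4.32% of the genes tested, and 26 of 98 (26.5%) in the deep libraries (Fisher's exact test, two-sided, p = 6.4e-07 and 9.24e-15), with a list drawn up after the 14 were seen, so neither p is independent evidence.

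In the run of 41 neighbouring genes 24 rose in each silver exposure, and 39 and 38 in the deep libraries. Handling shared by all exposed libraries would raise it with copper and zinc too, but the highest of those 4 medians was 0.454 in the deep libraries. 2 tests of depth or near-floor control values decided nothing: in fragments of the 8 genes long enough to count, the lowest silver library held 2.55 times the highest other deep library, between the bounds of 1 and 5, and in the median FPKM of all 41 it held 9.54 times, but the genes had been picked for their change with silver. Another test, added for that reason, picked the run of 41 neighbours with the highest change in the replicate 1 libraries alone (39 genes shared) and measured it in the others, where the lowest of 4 silver libraries held 9.25 times the highest of 9 other deep ones (84.7 and 9.16 FPKM), with 534176 to 1104460 fragments in the silver libraries and 464691 to 1286868 in the other deep ones, which argues against depth or near-floor values as the whole cause. Silver acting through the SOS response stays open as a hypothesis: the SOS list was higher with AgNP and Ag ion in the deep libraries (camera adjusted p = 0.0286 and 0.0239), but the higher of its adjusted p was 0.262 with an estimated correlation. Its member recA did not follow the run. In the deep libraries recA passed with Ag ion and copper ion but not with AgNP (means of 922.1, 848.5 and 702.8 FPKM, and 536.1 in controls). With copper ion the median of the run was -0.234 in these libraries.

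The 14 genes lower in all 6 exposures (a count of 5 without control replicate 1 and of 5 without control replicate 2) were weighed against 3 technical explanations. Removing each comparison's trend with gene length moved their median log2 change in the deep libraries from -1.61 to -1.502, which argues against length as the whole cause. Library scaling decided nothing when first tested: under median-of-ratios scaling of all libraries, 8 of the 14 were lower in all 6, between the bounds of 7 and 10, since 6 calls ended with CuO (median change -1.14 before and -1.18 after, median SE 0.242 and 0.336) and 3 with ZnO (-1.0 and -1.04, SE 0.232 and 0.323), where the SE grew and the change did not shrink. A second test of library scaling, added for that reason with the shallow libraries left out, gave 14 of 14. The first test took each library's factor over its genes above 0 alone, which leaves out many genes of the shallow libraries. That scaling moved the median changes of copper ion and zinc ion further down (-0.319 to -0.453 and -0.533 to -0.638). The shallow libraries may therefore have been scaled poorly in the first test. Control libraries made or processed apart from the exposed ones cannot be told apart from exposure: 11 genes hold values in all controls and are listed at 0 in all exposed libraries, and the labels give no batch, so an effect of the metals may not be separated from one of processing.

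Copper ion replicate 1 stood apart from its group. Its depth alone would leave its correlation with copper ion replicate 3 near that of replicate 2 thinned to the same depth, 0.72 to 0.755 in 100 draws, but it was 0.419; zinc ion replicate 2 lay within its own draws, at 0.68 against 0.676 to 0.72. Reads from the silver libraries would leave low the genes that are low there, but 31 genes low in all deep libraries, with means of 2.95 to 5.0 FPKM in the silver ones, reached 0.921 of the level of the phage-like run, which argues against such reads as the whole cause. Those genes averaged 87.5 FPKM in this library, 23.4 times their mean of 3.74 in the deep ones, which is consistent with an even background over genes such as DNA; zinc ion replicate 2 had 4.39. No biological explanation was tested.

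Other splits of the libraries were counted for each comparison, and the 10 splits of 3 against 3 are too few for a share under 0.05. In each, 1 of the 10, the real one, gave as many genes. The real count and the highest of the other splits were 80 and 0 for AgNP, 288 and 1 for Ag ion, 37 and 0 for CuO, 161 and 0 for copper ion, 108 and 0 for ZnO, 207 and 0 for zinc ion, 71 and 0 between the silver forms, 65 and 0 between the copper forms and 29 and 0 between the zinc forms. For genes changed in all 6 exposures, 1 of 100 regroupings, the real one, gave 14, and the highest other gave 0, a share under 0.05. Regroupings mix exposures within a group, and other splits of single comparisons already gave at most 1 gene. A count of 0 in all 6 at once was thus likely beforehand. The regroupings therefore exclude neither chance nor a shift of the 3 shared controls.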
